A study of Mus musculus with 24 samples.

How the data were processed

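The series holds 24 RNA-seq libraries of inguinal white adipose tissue, the subcutaneous fat pad of the groin, from male mice. The mice carried floxed alleles of Nr3c2, the gene of the mineralocorticoid receptor, and either no Cre recombinase (control) or Cre under the adiponectin promoter, which is active in fat cells (FMRKO, fat-specific mineralocorticoid receptor knockout). Mice of each genotype were on chow, on a high-fat diet or treated with corticosterone, the main glucocorticoid of the mouse, which gives 6 groups of 4 libraries. Per the labels' protocols, tissue was frozen in liquid nitrogen, RNA was extracted with TRIzol and a column kit, and libraries were made from total RNA after ribosomal RNA depletion (KAPA RiboErase). The dose and length of the corticosterone treatment, the fat content and length of the diet, and a vehicle group for corticosterone are not given in the sources used here, so both treatments were set against the chow groups. The titles of all 8 chow libraries carry a number ahead of the group and those of 0 of the other 16 do. The labels name no batch, but if this form marks one, it holds chow libraries only and cannot be told apart from the diet or from corticosterone in any comparison with chow.

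The deposited values used are counts of reads per gene, made by the authors with STAR 2.5.1a and featureCounts 1.4.6p-5 of the Subread package on the mouse build GRCm38, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads with several hits are not given in the sources used here. Each file also holds the authors' deposited CPM and RPKM columns, which were recomputed from the counts to check them and not used further. Whole-gene counts were available for 41388 genes, of which 97.3% have a symbol in GENCODE M21, and 99.85% of these overlap their M21 position in the coordinates of the files. Because strand use is not stated, reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies are uncertain where the counting could split their reads.

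Total counts per library ran from 17925109 to 40427675, and between 22249 and 24854 genes had at least 1 count in a library. At this depth the spread between libraries, not counting error, set the precision: the common dispersion was 0.113, a biological coefficient of variation of 34%. No pair of libraries within a group agreed within sampling noise in a chi-square test of their counts, so none was treated as a library deposited more than once. The labels number the libraries of a group and do not state that each is a separate animal, so p-values measure the spread between these libraries.

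Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 by group, which left 19717 genes. Libraries were scaled by TMM, dispersions were estimated with estimateDisp, and the quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all 24 libraries with 1 mean per group, 18 residual degrees of freedom and a prior of 2.81 degrees of freedom. The comparisons were FMRKO against control within each condition and averaged over the 3 conditions, high-fat diet or corticosterone against chow within each genotype, and the difference of the FMRKO effect between each treatment and chow. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. Adjusted p-values of genes are from this test unless another tool is named. CPM values in the text are TMM-normalised and given as mean ± SD with n = 4, and log2 fold changes are given with their standard error.

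Before the data were examined, 23 gene lists were fixed: glucocorticoid-responsive genes, mineralocorticoid-linked genes, corticosteroid receptors and enzymes, adipocyte identity, de novo lipogenesis, cholesterol synthesis, thermogenic fat, oxidative phosphorylation, fatty acid oxidation and TCA cycle, macrophages, inflammatory mediators, extracellular matrix, preadipocytes and stromal fibroblasts, endothelium, lymph node lymphocytes, skeletal muscle, epithelium, erythrocytes, Schwann cells, circadian clock, mitotic cell cycle, immediate-early genes, and genes flanking Adipoq. Some genes sit on more than 1 list, such as Fkbp5, Tsc22d3, Per1, Zbtb16 and Sgk1 on both steroid lists. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 23 lists, and again with an estimated correlation. Members past the per-gene threshold are counted over all genes tested and adjusted over the list alone. Mean log2 CPM over a list's members describes single libraries.

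The genes named in the text were chosen by a rule fixed at the same time. It allows Nr3c2, the other corticosteroid receptors and enzymes, and Adipoq, Lep, Pparg, Ucp1, Fkbp5, Tsc22d3, Per1, Zbtb16, Sgk1, Lcn2 and Ptgds to be named in any comparison, whatever their result. The text gives these genes in some comparisons only, and no values for Zbtb16 and Sgk1. The rule adds per comparison the 10 largest rises and 10 largest falls past the threshold, with a mean of at least 2 CPM, groups that do not overlap and no predicted name. From each list it takes up to 4 members past the threshold with the smallest adjusted p, or up to 2 with the smallest p, as values, where none passed. Ptgds did not pass the count filter. Genes outside the rule are said to have been chosen after their values were seen.

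The model was tested on simulated counts with the gene means and library sizes of the 24 libraries, of which 19436 genes passed the filter. Genes with a mean of at least 1 CPM were changed in the simulated chow FMRKO libraries. The model recovered 30% of genes changed by 1.5-fold, 63% of those changed by 2-fold and 85% of those changed by 4-fold. Of its 126 calls 6.3% were unchanged genes. Genes were drawn independently, without the lymph node and muscle differences of the real chow libraries. These shares therefore do not give the power of the real comparison. Alternatives were another scaling (relative log expression size factors), no filter and a stricter filter on low counts (1 CPM in 4 libraries), robust moderation of dispersions, the lymph node and muscle list scores as covariates, only the groups compared, the replicate number as a block, DESeq2 1.42.0, fry in place of camera, and leaving out each library in turn. Fits without the libraries rich in lymph node or muscle markers were added after seeing the data.

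Control and FMRKO groups share replicate numbers in the titles. In the high-fat diet groups the deviations from the group means correlated between libraries of the same number in 4 of 4 pairs (r from 0.20 to 0.72), and each library matched its own number best, so those groups were taken as paired, from the data and not from a statement in the labels. The main model has no term for these pairs, and its p-values treat the high-fat diet libraries as unpaired. Pairs enter only the fit with the replicate number as a block and the splits of the libraries. Numbers 1 and 4 are also the libraries rich in lymph node markers in both of these groups. Only 1 of 3 chow pairs and 0 of 4 corticosterone pairs had a correlation over 0.1, and these groups were not taken as paired.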

Results

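Gene expression was measured by total RNA sequencing in inguinal white fat of male mice with floxed Nr3c2 alleles, without Cre (control) or with Cre driven by the adiponectin promoter (FMRKO). Mice were on chow, on a high-fat diet or treated with corticosterone, with 4 libraries in each of the 6 groups. Total counts per library were 20274665 to 30060098 in chow controls and 17925109 to 29010546 in chow FMRKO mice. On the high-fat diet they were 24178074 to 31598597 in controls and 26431823 to 30741641 in FMRKO mice. In the corticosterone groups they were 24712325 to 40427675 in controls and 23275622 to 34799132 in FMRKO mice. Mitochondrial transcripts made up 2.72% to 5.49% of counts. Scd1, the stearoyl-CoA desaturase of fat, made up 5.8% to 11.3% of counts on the high-fat diet and 0.78% to 2.7% in the other groups.

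Nr3c2 (ENSMUSG00000031618, GRCm38 chromosome 8, 76899442 to 77245012, plus strand), the gene targeted by the knockout, was measured first in every library. On chow it lay at 23.7, 17.6, 23.8 and 28.7 CPM in control libraries 1, 2, 4 and 5. In chow FMRKO libraries 1, 2, 3 and 5 it was 11.3, 22, 17.7 and 25.8 CPM, so the groups overlapped. On the high-fat diet it was 18.5, 20.8, 25.0 and 18.9 CPM in controls and 14.3, 15.7, 15.4 and 12.7 CPM in FMRKO mice, with each FMRKO library below each control. With corticosterone it was 16.2, 18.4, 18.2 and 14.1 CPM in controls and 10.7, 7.7, 12.2 and 11.7 CPM in FMRKO mice, again without overlap. The log2 fold change of FMRKO against control was -0.29 ± 0.20 on chow, -0.52 ± 0.20 on the high-fat diet and -0.66 ± 0.20 with corticosterone (adjusted p = 0.592, 1.000 and 0.844). Averaged over the conditions it was -0.49 ± 0.11 (adjusted p = 0.287 in edgeR, 0.023 in DESeq2, and up to 1.000 over all settings). None of these passed the threshold in edgeR, which adjusts over all genes tested. Nr3c2 was fixed beforehand as the targeted gene, so missing that threshold does not show that it was unchanged. The chow value was 0.04 without the lymph node libraries (chow FMRKO 1 and 3 in this comparison), -0.10 without chow FMRKO 1, -0.16 without chow control 5 and -0.47 without chow FMRKO 5, so its direction is not settled. The counts cover the whole gene, including exons outside the floxed part, and cells other than adipocytes in the pad also contribute, so the size of the decrease does not measure deletion in fat cells.

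**Figure D1:**
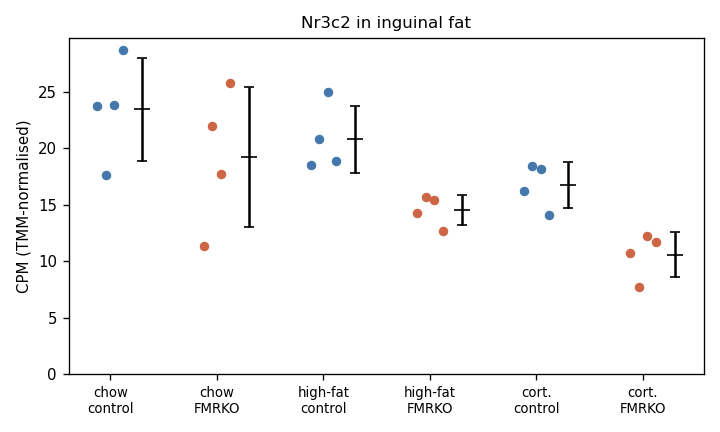
TMM-normalised CPM of Nr3c2 in each library (points; control blue, FMRKO orange), with the mean and SD of each group of 4 beside them. The FMRKO libraries lie below all controls on the high-fat diet (12.7 to 15.7 against 18.5 to 25.0 CPM) and with corticosterone (7.7 to 12.2 against 14.1 to 18.4 CPM), and overlap the controls on chow.

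Markers of neighbouring tissue separated some libraries from the rest of their group. The lymph node lymphocyte list (19 members tested, among them Cd3e and Ccr7) had a mean log2 CPM of 3.71 to 5.76 in 6 libraries, which were chow FMRKO 1 and 3, high-fat diet control 1 and 4, and high-fat diet FMRKO 1 and 4. It was 2.23 and 2.20 in corticosterone FMRKO 2 and 3 and between -1.25 and 1.27 in the other 16 libraries. The skeletal muscle list (17 tested, among them Ckm, Myh4 and Mylpf) reached 8.98 in chow FMRKO 5, 6.74 in corticosterone control 2 and 4.33 in high-fat diet control 3, against -0.13 to 2.00 elsewhere. The epithelium list (9 tested) stood at 2.16 in chow FMRKO 3 and at 2.5 and 2.21 in corticosterone FMRKO 3 and 4, against -2.5 to 0.32 in the other 21 libraries. Of the 4 chow FMRKO libraries, 3 were therefore rich in lymph node or muscle transcripts, and 0 of the 4 chow controls were.

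**Figure D2:**
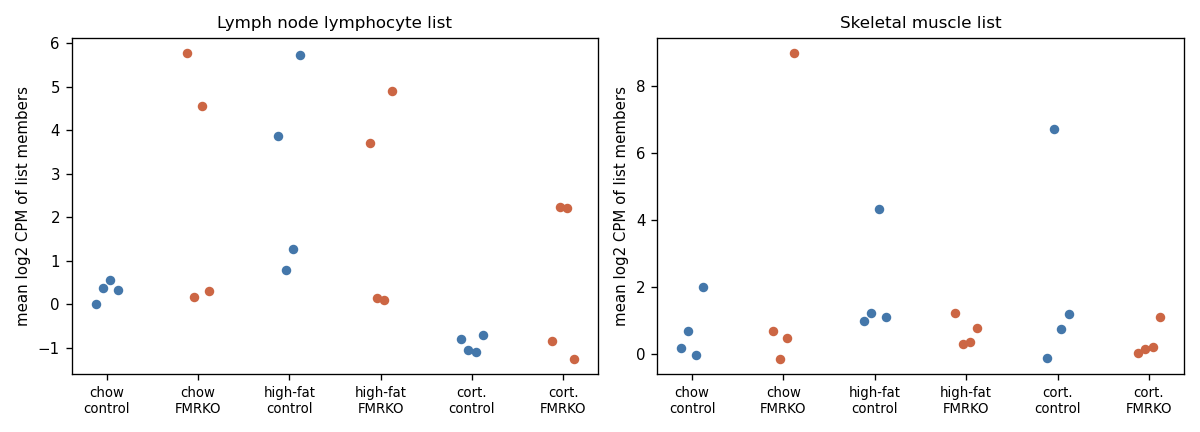
Mean log2 CPM of the lymph node lymphocyte list (left) and the skeletal muscle list (right) in each library, by group (control blue, FMRKO orange). For the lymphocyte list 6 libraries lie between 3.71 and 5.76, and for the muscle list chow FMRKO 5 lies at 8.98 and corticosterone control 2 at 6.74.

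The comparison of FMRKO with control mice on chow asks what loss of the receptor in fat does at rest. Zfp949, which codes for a zinc finger protein (ENSMUSG00000032425, chromosome 9, 88548020 to 88571061), was at 9.73 ± 0.407 CPM in controls and 26.7 ± 2.20 CPM in FMRKO mice (SD, n = 4), a log2 fold change of 1.46 ± 0.08. Eif4a2, a translation initiation factor (ENSMUSG00000022884, chromosome 16, 23107444 to 23114136), rose from 184 ± 18.2 to 282 ± 13.8 CPM, by 0.61 ± 0.09. These were the 2 genes past the threshold (adjusted p = 1.9e-09 and 0.006, edgeR quasi-likelihood test), both higher, while 2353 genes had an unadjusted p under 0.05 against 986 by chance. The count of 2353 became 1176 without the lymph node libraries, 1435 with the lymph node and muscle covariates and 2983 without the muscle libraries. Much of this excess therefore moves with the lymph node libraries. Adipoq (-0.10 ± 0.21), Lep (-0.23 ± 0.27), Pparg (-0.02 ± 0.24), Hsd11b1 (-0.35 ± 0.24) and the glucocorticoid-responsive Fkbp5 (-0.23 ± 0.31) did not pass. Camera called 11 of the 23 lists, with no member past the threshold in 10 of them. Among the higher ones were lymph node lymphocytes (median log2 fold change 4.42, 17 of 19 higher adjusted over the list alone) and skeletal muscle (6.86, 14 of 17), and among the lower ones macrophages (-0.69, 6 of 18 lower adjusted over the list alone) and extracellular matrix (-0.45, 0 of 19). Their adjusted p-values were 1.9e-10, 1.9e-05, 6.7e-07 and 6.7e-07, and 0.529, 0.685, 0.529 and 0.529 with an estimated correlation, with which 0 lists were called. The macrophage score was 4.05, 6.89, 5 and 6.11 in chow controls 1, 2, 4 and 5 against 4.65 to 5.39 in FMRKO mice, so its lower mean rests on controls 2 and 5. DESeq2 called 89 genes, including both, and the count was 19 without chow control 1. The call on Eif4a2 was lost without the lymph node libraries (0.63, adjusted p = 0.306), and its adjusted p ran from 1.1e-08 to 0.670 over all settings.

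On the high-fat diet the same pair of genes was higher in FMRKO mice. Zfp949 was at 7.79 ± 0.438 CPM in controls and 17.9 ± 0.621 CPM in FMRKO mice (log2 fold change 1.20 ± 0.08, adjusted p = 7.5e-08), and Eif4a2 at 126 ± 6.97 and 197 ± 12.1 CPM (0.65 ± 0.09, adjusted p = 0.002). No other gene passed in edgeR, and 781 genes had an unadjusted p under 0.05 against 986 by chance. Among genes that did not pass, Cfd, the adipocyte serine protease adipsin, had a log2 fold change of 0.98 ± 0.33, Pdgfra 0.50 ± 0.16 and Lep -0.28 ± 0.27 (adjusted p = 1.000 for each). Camera called 12 lists, with preadipocytes and stromal fibroblasts higher (median 0.18, adjusted p = 0.009) and immediate-early genes, skeletal muscle and cholesterol synthesis lower (-0.54, -1.44 and -0.16, adjusted p = 0.006, 0.006 and 0.015). With an estimated correlation 0 were called (adjusted p = 0.785 for each of these 4), and 0 of their members passed. High-fat diet control 3 stood apart for immediate-early genes (5.72, other libraries of both groups 3.89 to 4.5) and muscle (4.33, others 0.32 to 1.24), and the lower values move with it. With the replicate number as a block, which the high-fat diet libraries allowed, 6 genes were called, 1 of them shared, and the adjusted p of Eif4a2 was 0.081, within a range of 1.5e-08 to 1.000 over all settings. DESeq2 called 12. Without high-fat diet control 1, 2 or 3 or FMRKO 1 the lists called were 7, 6, 5 and 6.

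With corticosterone Zfp949 was again higher in FMRKO mice, at 16.7 ± 1.46 CPM against 8.36 ± 0.697 CPM in controls (1.00 ± 0.08, adjusted p = 2.1e-06), and was the 1 gene past the threshold. Eif4a2 was at 252 ± 12.6 against 176 ± 22.6 CPM, with a log2 fold change of 0.52 ± 0.09 that missed it (adjusted p = 0.054). Scnn1a, a subunit of the epithelial sodium channel, had 1.31 ± 0.38, Fkbp5 0.58 ± 0.31, the chemokine Cxcl10 1.15 ± 0.40 and Hsd11b1 -0.06 ± 0.24, and none of these passed (adjusted p = 0.825, 1.000, 0.992 and 1.000). Scnn1a was highest in the libraries rich in epithelial transcripts, at 6.41 and 4.46 CPM in corticosterone FMRKO 3 and 4 and 5.95 CPM in chow FMRKO 3, against 1.04 to 2.81 CPM elsewhere. Camera called 12 lists, among them mineralocorticoid-linked genes (12 tested, median 0.45, 1 higher adjusted over the list alone, adjusted p = 3.2e-05) and glucocorticoid-responsive genes (20 tested, 0.23, 0 adjusted over the list alone, adjusted p = 0.002) as higher. Lymph node lymphocytes were higher (2.94) and skeletal muscle lower (-5.19, 14 of 17 adjusted over the list alone), each with adjusted p = 4.8e-07. The former moves with corticosterone FMRKO 2 and 3 (2.23 and 2.20, the other 2 at -0.84 and -1.25) and the latter with corticosterone control 2 (6.74, other controls -0.1 to 1.21). Epithelium was higher (2.94, 5 of 9 adjusted over the list alone, adjusted p = 9.2e-04), and this moves with corticosterone FMRKO 3 and 4. With an estimated correlation the adjusted p-values were 0.271, 0.600, 0.529, 0.529 and 0.529. Of all genes 843 had an unadjusted p under 0.05, DESeq2 called 6 genes, and leaving out corticosterone control 1 gave 3, with Eif4a2 among those past the threshold.

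Averaged over the 3 conditions, 5 genes were higher and 2 lower in FMRKO mice. Zfp949 (1.22 ± 0.05, adjusted p = 1.1e-12) and Eif4a2 (0.59 ± 0.05, adjusted p = 9.8e-07) rose, and in each condition all 4 FMRKO libraries lay above the 4 controls. Gsta4, a glutathione transferase that acts on lipid peroxidation products (chromosome 9, 78191966 to 78209348), rose by 1.24 ± 0.18 (adjusted p = 0.003), from 13.9 ± 6.22 to 26.3 ± 5.75 CPM on chow, 13.3 ± 5.94 to 34.9 ± 8.37 on the high-fat diet and 11.3 ± 2.44 to 29.8 ± 2.09 with corticosterone. Ppm1m, a protein phosphatase, fell by 0.50 ± 0.08 on the log2 scale (adjusted p = 0.026) and Srprb, a subunit of the signal recognition particle receptor, by 0.41 ± 0.07 (adjusted p = 0.038). Both are also on chromosome 9, at 106194172 to 106199746 and 103188032 to 103202137. The other 2 higher genes were the predicted processed pseudogenes Gm11868 (1.82 ± 0.20) and Gm13841 (1.42 ± 0.20), chosen after their values were seen. Hsd11b1 (-0.22 ± 0.14), Tsc22d3 (0.19 ± 0.14), Lep (-0.16 ± 0.15) and Nr3c1, the glucocorticoid receptor (-0.03 ± 0.07), did not pass. Of the 8 tested genes flanking Adipoq, which were listed because the Cre transgene carries Adipoq sequence, 1 rose (Eif4a2; 2 adjusted over the list alone), with a median of -0.01 and a camera direction of up (adjusted p = 0.002, and 0.604 with an estimated correlation). Camera called 12 lists, 0 with an estimated correlation, and 6 without chow control 1 and 7 without chow FMRKO 3. DESeq2 called 34 genes, including all 7. The replicate block called 7 genes, 4 of them shared, without Ppm1m, Srprb and Gm13841, and the lymph node and muscle covariates called 8, 5 of them shared, without Ppm1m and Srprb. The call on Ppm1m was lost without chow control 4, chow FMRKO 1 or 5 or corticosterone FMRKO 3, and both calls were lost without the lymph node libraries (-0.45 and -0.44), without the muscle libraries (-0.50 and -0.38) and without both sets (-0.43 and -0.40). Of the pseudogenes, the call on Gm13841 was also lost without the lymph node libraries (1.30), and those on Gm13841 (1.22) and Gm11868 (1.75) without both sets. That left 4, 5 and 3 of the 7 calls shared in these 3 fits. The call on Srprb was also lost without any 1 of 14 libraries, which were chow control 1 and 4, chow FMRKO 1, 2 and 5, high-fat diet control 2 and 3, high-fat diet FMRKO 1, 2 and 4, corticosterone control 2 and 3 and corticosterone FMRKO 3 and 4.

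**Figure D3:**
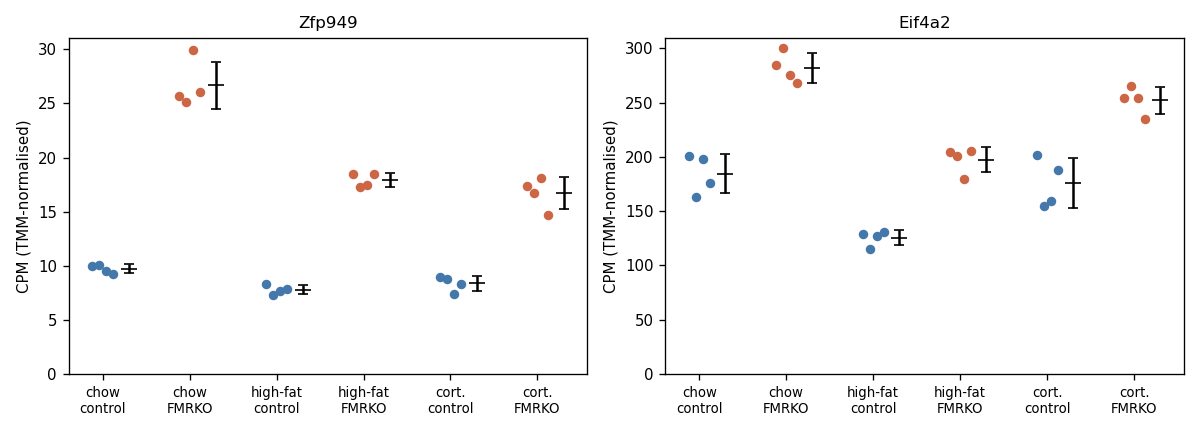
TMM-normalised CPM of Zfp949 (left) and Eif4a2 (right) in each library (points; control blue, FMRKO orange) with group mean and SD (n = 4). In each condition the 4 FMRKO libraries lie above the 4 controls, for Zfp949 at 14.7 to 29.9 against 7.29 to 10.1 CPM over all conditions.

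**Figure D4:**
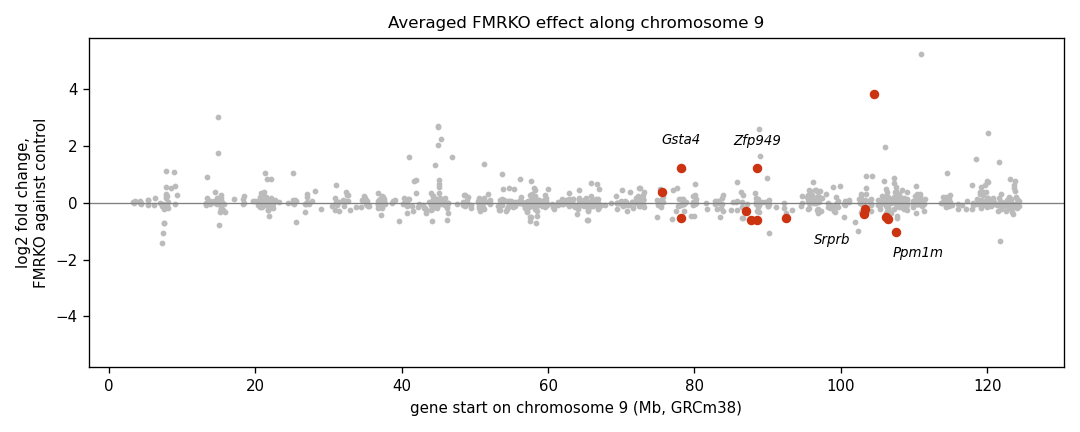
Averaged log2 fold change of FMRKO against control for each tested gene of chromosome 9, plotted at its start in megabases (GRCm38); red points have an unadjusted p under 0.001. The red points, which include Gsta4 (1.24), Zfp949 (1.22), Srprb (-0.41) and Ppm1m (-0.50), lie between 75.6 and 107.6 Mb.

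Across genes, the FMRKO effects of different conditions resembled each other little. Pearson's r of the log2 fold changes was -0.28 between chow and high-fat diet, 0.27 between chow and corticosterone and 0.00 between high-fat diet and corticosterone (Spearman's rho -0.22, 0.15 and 0.00), over 19717 genes that are not independent replicates. Zfp949 and Eif4a2 were called on chow and on the high-fat diet, and Zfp949 in all 3 conditions, where 0 shared calls were expected of independent lists. The value between chow and high-fat diet was -0.55 without high-fat diet FMRKO 4, 0.11 without high-fat diet control 4 and 0.05 without chow FMRKO 5. The value between high-fat diet and corticosterone was -0.21 and 0.25 without the former 2, and that between chow and corticosterone was -0.27 without the lymph node libraries.

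The difference of the FMRKO effect between the high-fat diet and chow, and between corticosterone and chow, was tested directly. In edgeR 0 genes passed in either test, with 1939 and 1171 genes at an unadjusted p under 0.05 against 986 by chance, and DESeq2 called 13 and 4. The count of 1939 became 1152 without the lymph node libraries, 1457 with the lymph node and muscle covariates and 2367 without the muscle libraries. For corticosterone against chow the difference was 0.81 ± 0.44 for Fkbp5, 0.91 ± 0.38 for Hsd11b2, 0.91 ± 0.41 for Per1 and -0.36 ± 0.28 for Nr3c2 (adjusted p = 0.860, 0.795, 0.818 and 0.939). For the high-fat diet against chow it was 0.55 ± 0.44 for Fkbp5 and -0.23 ± 0.28 for Nr3c2 (adjusted p = 0.677 and 0.801).

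The high-fat diet was set against chow in control mice to describe the diet itself. Lep, the hormone leptin, rose from 173 ± 64.8 to 1840 ± 392 CPM (3.41 ± 0.29, adjusted p = 7.0e-08), and the imprinted gene Mest, known to mark fat expansion, from 14.7 ± 7.03 to 925 ± 223 CPM (5.97 ± 0.45). Lipf (8.72 ± 0.77), Grid1 (7.43 ± 0.84), Tph2 (7.08 ± 0.67), Slc5a7 (6.92 ± 0.63) and Ncan (6.56 ± 0.57) rose most. Prtn3 (-4.85 ± 0.46), Ncam2 (-4.39 ± 0.37), Cyp2f2 (-4.27 ± 0.52), the amino acid transporter gene Slc43a1 (-3.92 ± 0.27), Cyp2e1 (-3.26 ± 0.37) and Cfd (-3.22 ± 0.35, from 16308 ± 3134 to 1744 ± 606 CPM) were among the largest falls. In total 3013 genes rose and 2745 fell, of which 896 and 909 changed at least 2-fold.

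In these control mice 14 of 18 cholesterol synthesis genes rose on the high-fat diet and 0 fell (17 rose adjusted over the list alone), with Lss 2.47 ± 0.18, Fdps 2.29 ± 0.21, Dhcr7 2.22 ± 0.16 and Mvd 2.15 ± 0.18 (list adjusted p = 7.2e-28, and 0.004 with an estimated correlation). Of de novo lipogenesis 9 of 17 rose and 2 fell (9 and 4 adjusted over the list alone), with Scd2 3.73 ± 0.23, Scd1 2.23 ± 0.34 and Acss2 2.10 ± 0.25. Of fatty acid oxidation and TCA cycle 11 of 19 rose (14), with Slc25a20 1.07 ± 0.18 and Idh3a 1.15 ± 0.24. Of oxidative phosphorylation 6 of 22 rose (3). Of thermogenic fat 6 of 13 rose and 1 fell (6 and 1), with Ucp1 4.79 ± 0.97, from 0.812 ± 1.39 to 23.2 ± 16.2 CPM, and Otop1 2.86 ± 0.66. The chow mean of Ucp1 rests on chow control 1 (2.89 CPM, the others 0 to 0.237), so the size of its rise is uncertain. Of circadian clock genes 10 of 17 fell and 1 rose (10 and 3), with Dbp -1.24 ± 0.26, Per3 -1.10 ± 0.22 and Nr1d2 -0.77 ± 0.14. These lists were called (adjusted p = 2.4e-05, 1.8e-04, 0.011, 0.038 and 0.011), as were lymph node lymphocytes (15 of 19 rose, 17 adjusted over the list alone, adjusted p = 0.013), but with an estimated correlation the adjusted p was 0.906 for all 6. The lymph node genes moved with high-fat diet control libraries 1 and 4, and without chow control 1 the lists called numbered 11 in place of 7. Lists not called by camera held Hsd11b1 (-0.74 ± 0.25) and Nr3c1 (-0.31 ± 0.12) among receptors and enzymes (2 of 8 fell, 0 adjusted over the list alone; median -0.21, mean 0.05, test down). The call on Hsd11b1 was lost without chow control 4 or 5 or high-fat diet control 2, and that on Nr3c1 without chow control 1 or 5 or high-fat diet control 4. Other such lists held Cdkn1a (1.41 ± 0.27), Arrdc2 (1.30 ± 0.23), Klf15 (-1.53 ± 0.27) and Klf9 (-0.93 ± 0.21) among glucocorticoid-responsive genes (6 of 20 rose, 3 fell; 6 and 4 adjusted over the list alone). Only the groups compared gave 3458 genes and the replicate block 3428.

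In FMRKO mice the high-fat diet gave 3002 higher and 1811 lower genes, with 647 and 520 changed at least 2-fold. Lep rose from 148 ± 41.2 to 1516 ± 380 CPM (3.36 ± 0.29, adjusted p = 1.1e-07), Mest by 5.95 ± 0.45, Lipf by 8.67 ± 0.81, Ncan by 6.64 ± 0.57, Tph2 by 5.96 ± 0.64, Pla2g2e by 4.79 ± 0.37 and Ucp1 by 4.60 ± 0.98. Mup10 (-5.76 ± 1.04), Cyp2f2 (-3.84 ± 0.51), Prtn3 (-3.59 ± 0.43), Ncam2 (-3.32 ± 0.35), Cyp2e1 (-2.89 ± 0.37) and Cfd (-1.87 ± 0.33) fell. Cholesterol synthesis rose in 14 of 18 genes (14 adjusted over the list alone), with Lss 2.35 ± 0.18, Fdps 2.28 ± 0.21 and Nsdhl 2.18 ± 0.20 (list adjusted p = 2.6e-27, and 0.005 with an estimated correlation). De novo lipogenesis rose in 10 of 17 and fell in 1 (10 and 1), with Scd2 3.77 ± 0.23 and Acss2 2.58 ± 0.26. Adipocyte identity rose in 8 of 23 and fell in 1 (11 and 1), with Agpat2 2.06 ± 0.31 and Dgat2 2.09 ± 0.32. Endothelium rose in 5 of 10 (5), with Cldn5 1.77 ± 0.24 and Cdh5 0.84 ± 0.17. Erythrocyte genes rose in 4 of 5 (5), with Hba-a1 1.58 ± 0.32, and circadian clock genes fell in 8 of 17 and rose in 1 (9 and 1), with Bhlhe41 -1.40 ± 0.20 and Dbp -1.40 ± 0.26. Oxidative phosphorylation rose in 10 of 22 (12) and fatty acid oxidation and TCA cycle in 8 of 19 (10; adjusted p = 0.002 and 2.2e-04, and 0.788 for both with an estimated correlation). The 5 lists before these were called (adjusted p = 1.0e-09, 0.002, 0.005, 0.005 and 0.002), with 0.474, 0.788, 0.788, 0.788 and 0.701 with an estimated correlation. Extracellular matrix rose in 5 of 19 (5; adjusted p = 0.019, and 0.788 with an estimated correlation), with Sparc 1.24 ± 0.19 and Lox 1.29 ± 0.23. Of the mitotic cell cycle 1 of 12 rose (0 adjusted over the list alone; 0.031 and 0.788). Of skeletal muscle 14 of 17 fell (14; median -6.14, adjusted p = 0.044, and 0.788 with an estimated correlation), with Mylpf -6.85 ± 1.94 and Eno3 -3.86 ± 0.99, genes whose calls were lost without chow FMRKO 5, the library rich in muscle transcripts. Of immediate-early genes 2 of 10 fell (1 rose and 2 fell adjusted over the list alone) and the list was not called (adjusted p = 0.389). Without the lymph node and muscle libraries, which leaves 1 chow FMRKO library assumed to vary like the other groups, 1926 genes were called, and 3202 with only the groups compared.

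The high-fat diet changes of the 2 genotypes, which share no libraries, had r = 0.31 and rho = 0.46 across genes, with r = 0.12 without high-fat diet FMRKO 4. Of the genes called in both, 2121 rose in both against 458.7 expected of independent lists, 1167 fell in both against 252.1, and 3 went opposite ways. Camera called the difference between the genotypes for 10 of the 23 lists. The change was lower in FMRKO mice for lymph node lymphocytes (1.1e-10), skeletal muscle (1.5e-08), epithelium (0.002) and thermogenic fat (0.039). The first 3 of these move with single chow FMRKO libraries, which were 1 and 3 for lymphocytes, 5 for muscle and 3 for epithelium, and muscle also with high-fat diet control 3. Thermogenic fat was uneven on chow too, at 2.86 in FMRKO 5 (other FMRKO libraries 1.17 to 2.08) and 2.63 in control 1 (other controls 1.18 to 1.98). The change was higher in FMRKO mice for extracellular matrix (5.6e-07), preadipocytes and stromal fibroblasts (2.3e-05), macrophages (2.6e-05), endothelium (8.5e-04), glucocorticoid-responsive genes and erythrocytes (0.003 each, all adjusted p). On chow, macrophages (6.89 and 6.11) and matrix (9.22 and 8.77) stood in controls 2 and 5 above each FMRKO library (up to 5.39 and 8.53), while the other 2 controls were at 4.05 and 5 for macrophages and 8.02 and 8.53 for matrix, so both differences lean on controls 2 and 5. Endothelium was at 5.82 and 5.92 in chow FMRKO 1 and 3, the lymph node libraries, against 6.25 to 6.59 in the other chow libraries. Glucocorticoid-responsive genes were at 6.83 in chow control 4, against 5.89 to 6.2 in the other chow controls and 5.73 to 6.14 in chow FMRKO libraries. That difference leans in part on chow control 4. With an estimated correlation 0 were called (adjusted p = 0.583 for macrophages, 0.594 for glucocorticoid-responsive genes, 0.716 for thermogenic fat and 0.486 for the other 7).

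Corticosterone was set against chow in control mice to describe the glucocorticoid response. Hsd11b1, the enzyme that regenerates active glucocorticoid inside cells, rose from 79.7 to 590 ± 207 CPM (2.89 ± 0.26, adjusted p = 8.8e-08), and H6pd, which supplies its cofactor, by 0.96 ± 0.15. Lep rose from 173 ± 64.8 to 2775 ± 613 CPM (4.00 ± 0.30), and Fkbp5, a chaperone partner of the steroid receptors, from 117 ± 60.6 to 274 ± 95.5 CPM (1.23 ± 0.32, adjusted p = 0.004). Tsc22d3 rose by 1.90 ± 0.25, Cdkn1a by 2.51 ± 0.28, Hif3a by 3.09 ± 0.46 and Angptl4 by 1.27 ± 0.19. The largest rises also held Rnase2a (8.21 ± 1.19), Hspb7 (7.13 ± 0.64), Gabrr2 (5.57 ± 0.40) and Mogat2 (4.50 ± 0.43), and the largest falls Gbp11 (-4.34 ± 0.79), the chemokine Ccl8 (-4.28 ± 0.75), Prtn3 (-3.97 ± 0.44), Celsr2 (-3.94 ± 0.35), Mx1 (-3.46 ± 0.86) and Cfd (-3.45 ± 0.35). In total 3986 genes rose and 4467 fell, of which 838 and 2161 changed at least 2-fold. The median of all genes was -0.116, and -0.108 in FMRKO mice, so changes are relative to a shift of that size.

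In the corticosterone controls 20 of 22 oxidative phosphorylation genes rose (21 adjusted over the list alone), with Atp5d 0.86 ± 0.15 and Cox5a 0.91 ± 0.18. There, 15 of 18 cholesterol synthesis genes rose (15), with Hmgcs1 2.67 ± 0.31, Sc5d 2.12 ± 0.22 and Dhcr7 1.65 ± 0.15. Of adipocyte identity 11 of 23 rose and 2 fell (11 and 2), with Dgat2 2.22 ± 0.32. Of de novo lipogenesis 7 of 17 rose (8 rose and 1 fell), with G6pdx 1.98 ± 0.15 and Thrsp 2.07 ± 0.38. Of fatty acid oxidation and TCA cycle 12 of 19 rose and 1 fell (13 and 1), with Acaa2 1.25 ± 0.18. All 5 erythrocyte genes rose (5), with Hbb-bs 1.90 ± 0.32. Of glucocorticoid-responsive genes 9 of 20 rose and 2 fell (9 and 4), and 9 did not pass over all genes tested. The median log2 fold change of that list was 0.18, so the rises named for corticosterone controls do not describe all of it. Endothelium fell in 9 of 10 (9), with Tie1 -1.28 ± 0.16, Emcn -1.14 ± 0.16 and Pecam1 -0.77 ± 0.10. Preadipocytes and stromal fibroblasts fell in 11 of 16 and rose in 2 (11 and 2), with Clec3b -1.29 ± 0.22, Pdgfrb -1.06 ± 0.15, Pdgfra -1.03 ± 0.16 and Zfp423 1.08 ± 0.19. Camera called these 9 lists with adjusted p-values from 6.8e-11 for cholesterol synthesis to 0.015 for glucocorticoid-responsive genes, and 0 with an estimated correlation (adjusted p = 0.195 for cholesterol synthesis and 0.736 for the other 8). Circadian clock genes fell in 8 of 17 and rose in 3 (10 and 4; adjusted p = 0.053, and 0.736 with an estimated correlation), with Dbp -3.13 ± 0.28, Nr1d2 -1.56 ± 0.15 and Nfil3 1.71 ± 0.22. Extracellular matrix fell in 9 of 19 and rose in 4 (9 and 4; adjusted p = 0.095), with Col1a2 -2.00 ± 0.34, Mmp2 -1.56 ± 0.28 and Lox 2.12 ± 0.24. Of inflammatory mediators 5 of 18 fell and 1 rose (5 and 1; adjusted p = 0.890), with Cxcl10 -1.62 ± 0.40, and of macrophages 2 of 18 fell (0 adjusted over the list alone; 0.671). Nr3c2 had a log2 fold change of -0.49 ± 0.20 (adjusted p = 0.051) and Ucp1 of 0.45 ± 0.90 (adjusted p = 0.714). The Ucp1 value depends on a chow mean that rests on chow control 1 (2.89 CPM, the others 0 to 0.237).

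In FMRKO mice corticosterone gave 3989 higher and 4113 lower genes, with 842 and 1954 changed at least 2-fold. Hsd11b1 rose from 62.4 ± 12.1 to 565 ± 169 CPM (3.18 ± 0.26, adjusted p = 4.0e-08), Lep from 148 ± 41.2 to 2853 ± 176 CPM (4.27 ± 0.30) and Fkbp5 from 99.2 ± 31.1 to 410 ± 65.2 CPM (2.05 ± 0.32, adjusted p = 6.2e-05). Tsc22d3 (2.23 ± 0.26), Cdkn1a (3.03 ± 0.29), Hif3a (3.85 ± 0.47), Lcn2 (2.51 ± 0.66) and H6pd (1.06 ± 0.15) rose, and Nr3c2 fell by 0.85 ± 0.20 on the log2 scale (adjusted p = 0.002). Hspb7 (6.87 ± 0.63), Map7d2 (5.66 ± 0.66), Hmga2 (4.92 ± 0.84) and Cpne9 (4.90 ± 0.42) were among the largest rises and Ccl5 (-4.41 ± 1.00) and Prtn3 (-4.26 ± 0.44) among the largest falls. Muscle genes such as Myh8 (-6.88 ± 1.72), Pygm (-6.20 ± 1.59) and Casq1 (-6.13 ± 1.54) made up most other large falls, and their calls were lost without chow FMRKO 5.

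Of the gene lists in corticosterone FMRKO mice, oxidative phosphorylation rose in 20 of 22 (21 adjusted over the list alone), cholesterol synthesis in 15 of 18 (15), erythrocytes in 5 of 5 (5), and glucocorticoid-responsive genes in 9 of 20 with 1 fall (9 and 1). Adipocyte identity rose in 13 of 23 with 2 falls (14 and 2). Macrophage genes rose in 11 of 18 (11), with Cd68 1.93 ± 0.46, Lgals3 1.95 ± 0.47, C1qc 1.02 ± 0.23 and Atp6v0d2 2.70 ± 0.69. Mineralocorticoid-linked genes rose in 4 of 12 with 1 fall (4 and 1), with Ndrg2 1.93 ± 0.26. Schwann cell genes fell in 5 of 7 (6), with Ncmap -2.53 ± 0.55. Lymph node lymphocytes fell in 7 of 19 (10) and clock genes in 9 of 17 with 4 rises (9 and 4), with Dbp -3.05 ± 0.28 and Clock 0.82 ± 0.13. All 10 of these were called, with adjusted p-values from 4.6e-10 for cholesterol synthesis to 0.048 for lymph node lymphocytes, and 0 with an estimated correlation. The adjusted p was then 0.251 for cholesterol synthesis, 0.384 for erythrocytes and 0.623 to 0.849 for the others. De novo lipogenesis rose in 8 of 17 and fell in 2 (9 and 2), and fatty acid oxidation and TCA cycle rose in 11 of 19 and fell in 1 (12 and 1; adjusted p = 6.3e-04 and 7.1e-04, and 0.623 and 0.647 with an estimated correlation). The fall of lymph node genes moved with chow FMRKO libraries 1 and 3, and without the lymph node and muscle libraries 3154 genes were called. Endothelium fell in 4 of 10 and rose in 1 (4 and 1; adjusted p = 0.061), preadipocytes and stromal fibroblasts fell in 8 of 16 and rose in 2 (9 and 2; 0.076), and epithelium changed in 0 of 9 (0; 0.845). The difference between the genotypes was called by camera for 10 of the 23 lists. The smallest adjusted p was that of skeletal muscle (1.3e-13, change lower in FMRKO mice), which moves with chow FMRKO 5 and corticosterone control 2, then those of endothelium (2.3e-08, higher), macrophages (2.0e-07, higher), glucocorticoid-responsive genes (9.0e-05, higher) and extracellular matrix (1.5e-04, higher). Those of macrophages and matrix lean on chow controls 2 and 5, and in endothelium chow FMRKO 1 and 3 stood lowest of the chow libraries, as for the high-fat diet. That of glucocorticoid-responsive genes leans in part on chow control 4 (6.83, other chow libraries 5.73 to 6.2). Preadipocytes and stromal fibroblasts (0.007), mineralocorticoid-linked genes and erythrocytes (0.008 each) were higher, and lymph node lymphocytes and Schwann cells (0.008 each) lower, the former with chow FMRKO 1 and 3. With an estimated correlation 0 were called (adjusted p = 0.474 for endothelium, 0.968 for lymph node lymphocytes and 0.491 for the other 8).

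**Figure D5:**
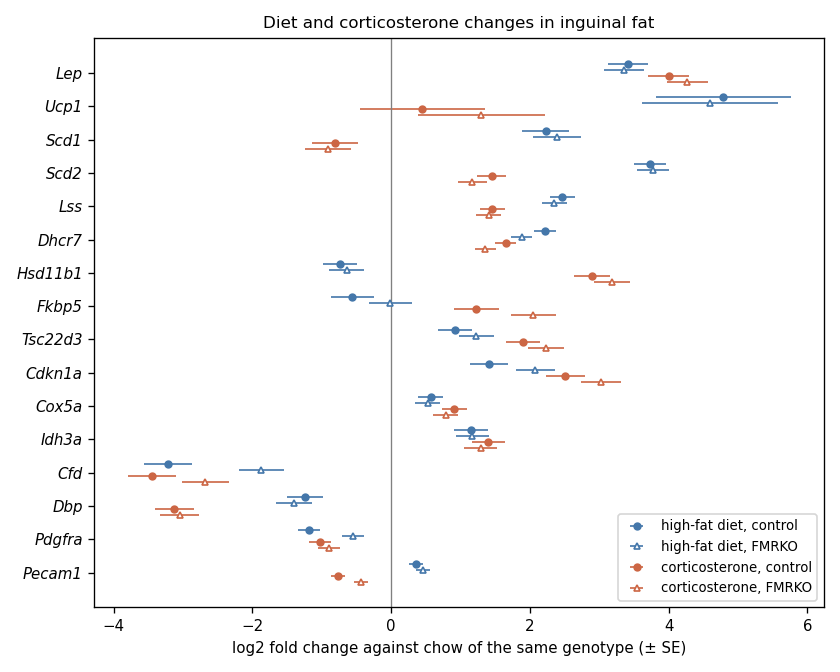
Log2 fold change against chow of the same genotype, with its standard error, for 16 genes on the high-fat diet (blue) and with corticosterone (orange), in control (circles) and FMRKO mice (open triangles). Lep rose in all 4 comparisons (3.36 to 4.27), Cfd fell in all 4 (-3.45 to -1.87), Ucp1 rose on the high-fat diet, and Hsd11b1 rose with corticosterone (2.89 and 3.18).

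The corticosterone changes of the 2 genotypes had r = 0.60 and rho = 0.77 across genes. Of the genes called in both, 3285 rose in both against 806.4 expected of independent lists, 2803 fell in both against 931.8, and 3 went opposite ways.

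The changes on the high-fat diet and with corticosterone were compared in control mice, where both use the 4 chow libraries. Across genes r was 0.37 and rho 0.47. Of the genes called in both, 2115 rose in both against 609.1 expected of independent lists and 1712 fell in both against 621.9, among them the falls of Cfd (-3.22 and -3.45), Prtn3 (-4.85 and -3.97) and Dbp (-1.24 and -3.13) and the rises of Lep (3.41 and 4.00), Lss (2.47 and 1.46) and Cdkn1a (1.41 and 2.51), and 136 went opposite ways. Simulated unchanged groups, set against simulated chow libraries with the real chow means and library sizes, gave r of 0.47 to 0.54 and rho of 0.44 to 0.47 by shared chance alone. Genes were drawn independently. Differences in cell content between the real chow libraries, such as macrophage scores from 4.05 to 6.89, are therefore not in these values. The covariance of the fold changes was 0.366 against a simulated mean of 0.133 (0.12 to 0.145 in 20 simulations), a difference of 0.233. With the chow libraries split 2 and 2, in 6 ways, r was 0.19 to 0.31, the covariance 0.249 to 0.344, and 1110 to 1530 genes rose and 790 to 1054 fell in both.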

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

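The tests of a linked stretch of chromosome 9, of extra copies of genes beside Adipoq, of processed copies of chromosome 9 genes, and of loss of the receptor were chosen only after the result was seen, while those of node stroma and of Eif4a2 copies were written before it.

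In 234 groups of 4 libraries, 15 single libraries lay far from the others of their group (a gap above Dixon's 95% critical value), and chance alone gives about 1 in 20 groups. Skeletal muscle transcripts (mean log2 CPM) were highest in chow FMRKO 5 at 8.98 (others -0.13 to 0.71), in high-fat diet control 3 at 4.33 (1.00 to 1.23) and in corticosterone FMRKO 4 at 1.12 (0.05 to 0.23). High-fat diet control 4 was lowest for de novo lipogenesis at 8.28 (8.99 to 9.08) and for thermogenic fat at 2.26 (3.29 to 3.46), and is the library of its group with the highest lymphocyte score, 5.72. Chow FMRKO 1, with the highest lymphocyte score of its group at 5.76, was lowest for glucocorticoid-responsive genes at 5.73 (6.07 to 6.14). Cholesterol synthesis was highest in chow FMRKO 5 at 3.95 (3.56 to 3.6), and inflammatory mediators in high-fat diet FMRKO 4 at 2.47 (2.15 to 2.19). Schwann cell genes were lowest in corticosterone FMRKO 2 at 1.59 (2.22 to 2.32), circadian clock genes highest in corticosterone control 1 at 5.13 (4.89 to 4.92) and immediate-early genes lowest in chow control 4 at 4.20 (4.75 to 4.81). In CPM, Eif4a2 was lowest in high-fat diet FMRKO 3 at 180 (201 to 205) and Gsta4 highest in corticosterone control 1 at 14.9 (9.97 to 10.1). Srprb was highest in corticosterone FMRKO 2 at 26.2 (18.1 to 19.1) and Ucp1 in chow control 1 at 2.89 (0 to 0.237).

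Lymphocyte markers were high in 6 libraries of 3 groups. A separate list of lymph node stroma genes (10 tested, among them Ccl19, Glycam1 and Coch) had a mean log2 CPM of 1.43 to 2.81 in these libraries and -0.76 to 1.24 in the other 18, so 6 of 6 lay above all others. The next highest were corticosterone FMRKO 2 and 3 (1.24 and 1.09), which also had the next highest lymphocyte scores (2.23 and 2.20). The inguinal pad holds a lymph node, and node tissue in the dissected pad is a candidate source of these transcripts, with 6 libraries as it needs. The same value, 6, argues against lymphocytes that entered the fat without node tissue as the whole source. This holds only as far as the listed genes are made by node stroma and not by the lymphocytes themselves, which was not tested. No biological explanation in terms of the groups was tested, and 2 of 4 chow FMRKO libraries against 0 of 4 chow controls means that the chow comparison carries this difference.

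Zfp949, Gsta4, Ppm1m and Srprb lie on chromosome 9 and Eif4a2 lies beside Adipoq, whose promoter drives the Cre transgene. Among genes not called in the averaged comparison, 10 of 1069 on chromosome 9 and 20 of 18641 elsewhere had p below 0.001 (0.94% against 0.11%, Fisher exact p = 2.3e-06), so a linked stretch of chromosome 9 that came with the Cre transgene may be a source of these differences. Rfc4, next to Eif4a2, had an averaged log2 fold change of 0.47 (0.20 to 0.75, adjusted p = 0.626), but it overlaps the end of Eif4a2 from 23113943 to 23114136 and might take its reads, and the other neighbours Hrg (0.06), St6gal1 (0.09, -0.33 to 0.50), Masp1 (-0.08), Fetub (-0.31), Kng2 (-0.35) and Kng1 (-0.60) had intervals that include 0, so extra copies of genes beside Adipoq on the transgene stay open. Reads shared between Eif4a2 and the 2 called pseudogenes, Gm11868 and Gm13841 (chosen after their values were seen), are argued against, since 0% of either aligned to Eif4a2, while they are at least 98% identical to Cyb5r4 (-0.29 ± 0.06) and Rpl29 (-0.58 ± 0.12) on chromosome 9. Loss of the mineralocorticoid receptor in fat cells cannot be told apart from effects of the transgene, because 0 groups carry Cre without floxed alleles.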

How the results depend on the processing

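The fits without the lymph node libraries, without the muscle libraries and without both were tests chosen only after the result was seen, and the other alternatives were not. Without both, chow FMRKO keeps 1 library, which is assumed to vary like the other groups. Restriction to the groups compared leaves the averaged comparison as it is and gives no value of its own. The cause was not tested for any change named here, except that leaving out libraries or fitting only the groups compared leaves fewer samples.

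Many named genes were chosen for large changes or small adjusted p in these same data, so their counts do not stand for all calls. Of the 350 called values of named genes, 349 stayed past the threshold in the same direction with relative log expression size factors, 340 without the filter on low counts, and 347 with robust dispersions. With the stricter filter 346 did and 0 lost the threshold, with DESeq2 333 did and 0 lost it, and with only the groups compared 301 did and 37 lost it, the rest having no value there. With lymph node and muscle covariates 317 did, with the replicate block 280, without the muscle libraries 323, without the lymph node libraries 304 and without both 245. Zfp949 stayed past the threshold in all alternatives in each FMRKO comparison, and Gsta4 and Eif4a2 did averaged over conditions. Of all 5758 genes called for the high-fat diet in controls, 5625 were also called with relative log expression size factors. With only the groups compared 3351 were, and with the replicate block 3330. For corticosterone in controls these numbers were 8187, 7601 and 6124 of 8453.

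DESeq2 called 89, 12, 6 and 34 genes for FMRKO on chow, on the high-fat diet, with corticosterone and averaged, and 13 and 4 for the differences of high-fat diet and corticosterone from chow. Only the groups compared gave 1, 1 and 2 genes for FMRKO in the 3 conditions, and 3458 and 3202 for the high-fat diet in controls and FMRKO mice. The replicate block gave 1 gene for FMRKO on chow, 6 on the high-fat diet and 3428 for the high-fat diet in controls, and the stricter low-count filter gave 3 for FMRKO with corticosterone. Over all groups 11 of 23 library pairs of the same number correlated over 0.1, and 8 matched their own number best. Without the lymph node libraries 1, 1 and 4 genes were called for FMRKO on chow, on the high-fat diet and averaged. Without the lymph node and muscle libraries there were 1 on the high-fat diet, 4 averaged, 1926 for the high-fat diet and 3154 for corticosterone in FMRKO mice, and 1 for the difference of corticosterone from chow.

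Nr3c2 in FMRKO mice on chow reversed to 0.04 without the lymph node libraries, averaged over conditions it was -0.49 in DESeq2, where it passed the threshold, and on the high-fat diet in controls it was 0.01 without the lymph node and muscle libraries. For corticosterone in FMRKO mice, without the lymph node libraries Cd3e was 0.90, Fcer2a 0.85 and Cd3g 1.03, and without the lymph node and muscle libraries these were 1.16, 0.72 and 1.36, Lck 0.38, Eno3 0.42 and Tnnt3 0.26, all reversed.

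With an estimated inter-gene correlation the gene lists called were 0, 0, 0 and 0 for FMRKO on chow, on the high-fat diet, with corticosterone and averaged, 1 and 1 for the high-fat diet in controls and FMRKO mice, and 0 and 0 for corticosterone. With fry they were 0, 0, 0 and 0 for FMRKO, and 3 and 5 for the high-fat diet. For corticosterone, fry also called lists in both genotypes. Examples are cholesterol synthesis (fry adjusted p = 8.6e-07 in controls and 3.4e-06 in FMRKO mice) and oxidative phosphorylation (0.005 and 0.006). Others did not pass, such as extracellular matrix (0.092 and 0.926) and mitotic cell cycle (0.973 and 0.437). Fry asks whether members changed at all, and camera whether they changed more than other genes. With lymph node and muscle covariates they were 7, 7, 5 and 3 for FMRKO. On chow the replicate block gave 7. Without the lymph node libraries 4 were called for FMRKO on the high-fat diet and 1 averaged, and without the lymph node and muscle libraries 4 on chow, 4 on the high-fat diet, 3 averaged and 6 for the high-fat diet in FMRKO mice.

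Agreement of chow and corticosterone FMRKO effects was -0.27 without the lymph node libraries and -0.03 without the lymph node and muscle libraries. For the high-fat diet in both genotypes r was 0.61 with covariates. For corticosterone it was 0.31 with no low-count filter, 0.75 with only the groups compared, 0.46 without the lymph node libraries and 0.41 without the lymph node and muscle libraries. For high-fat diet and corticosterone in controls it was 0.57 with covariates and 0.53 without the lymph node libraries.

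Leaving out each library in turn gave 2 to 19 genes for FMRKO on chow (19 without chow control 1), 2 to 3 on the high-fat diet, 1 to 3 with corticosterone (3 without corticosterone control 1) and 5 to 10 averaged. It gave 4457 to 6069 and 3310 to 5235 for the high-fat diet in controls and FMRKO mice, 7150 to 8478 and 6860 to 8161 for corticosterone, and 0 to 0 for both differences in edgeR. Nr3c2 ran from -0.47 to -0.10 on chow, -0.57 to -0.43 on the high-fat diet, -0.75 to -0.55 with corticosterone and -0.55 to -0.43 averaged. Lists called ran from 8 to 13, 5 to 10, 8 to 14 and 6 to 13 for FMRKO, 5 to 11 and 9 to 11 for the high-fat diet, and 9 to 11 and 11 to 13 for corticosterone. Agreement ran from -0.55 to 0.11 for chow and high-fat diet, 0.15 to 0.44 for chow and corticosterone, -0.21 to 0.25 for high-fat diet and corticosterone, 0.12 to 0.42 for the high-fat diet between genotypes, 0.57 to 0.68 for corticosterone and 0.32 to 0.47 for the treatments in controls. Of the values of called genes 2673 stayed past the threshold and 239 did not.

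Depth limits genes with few counts. The Ucp1 values on chow rest on few reads per library. Rfc4 had far fewer reads than Eif4a2 (2.56 against 203 CPM), but the standard error of its averaged log2 fold change was 0.13.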

Other observations

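The interferon and complement lists, the gene families, the batch of the chow libraries and the averaged splits that part the high-fat diet pairs were tests chosen only after the result was seen, and the other tests of this part were not.

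Interferon-stimulated genes fell with corticosterone in 14 of 19 members in control mice (median log2 fold change -1.34, camera adjusted p = 5.1e-04, and 0.629 with an estimated correlation) and in 0 of 19 in FMRKO mice (-0.15, 0.395). Mx1 fell by 3.46 ± 0.86 on the log2 scale in controls and had -0.55 ± 0.77 in FMRKO mice, Oasl2 -2.47 ± 0.56 and -0.15 ± 0.53, and Mx2 -2.69 ± 0.48 and -0.63 ± 0.44. The difference between the genotypes was not tested for this list as a whole. In the edgeR test of that difference for single genes, 0 of 19717 genes passed (smallest adjusted p = 0.418), so a response that depends on genotype is not shown. On the high-fat diet 1 of 19 members fell in controls and 0 in FMRKO mice (adjusted p = 0.121 and 0.233).

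Complement genes fell with corticosterone in 9 of 16 members and rose in 1 in control mice (median -0.62, adjusted p = 5.1e-04, and 0.491 with an estimated correlation), and in FMRKO mice 7 fell and 1 rose (-0.51, 0.018, and 0.570 with an estimated correlation). In corticosterone controls C2 had -2.15 ± 0.20, C4b -1.55 ± 0.16, C3 -1.15 ± 0.22 and Cd59a 0.99 ± 0.21. On the high-fat diet 9 fell and 2 rose in controls (adjusted p = 0.024, and 0.570 with an estimated correlation) and 3 fell and 2 rose in FMRKO mice (0.395).

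Of 252 gene families of 8 to 150 members, tested in 4 comparisons (1008 tests), 0 passed in camera with an estimated correlation, with 56 tests at an unadjusted p under 0.05 and a smallest adjusted p of 0.408. With the preset correlation 126 tests passed.

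The changes on the high-fat diet and with corticosterone resembled each other in control mice. Their covariance was 0.366 against 0.12 to 0.145 in simulations of unchanged groups, while r (0.37) lay below its simulated range of 0.47 to 0.54 and rho (0.47) at the upper end of 0.44 to 0.47, so the correlations alone do not part the changes from shared chance. With the chow libraries split 2 and 2, so that none was shared, the covariance was 0.249 to 0.344 and r 0.19 to 0.31, which argues against chance values of the shared chow libraries as the whole source. A batch of the chow libraries set apart from the others may add to the resemblance and cannot be told apart from a shared biological response, since 0 of the 8 chow libraries have titles of the form of the other 16. The same holds for every high-fat diet and corticosterone change against chow and for its likeness in the 2 genotypes (3285 shared rises and 2803 shared falls with corticosterone, 2121 and 1167 on the high-fat diet). There the splits that argue against chance do not exclude such a batch.

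Other splits of the same libraries were counted for each comparison. For FMRKO against control on chow, 4 of 35 splits gave at least the 2 genes of the real split (highest other 267), so chance cannot be excluded for this count. On the high-fat diet, where the libraries were taken as paired by number from these same data, 2 of 35 splits gave at least the 2 genes of the real split (highest other 1750). The other of these keeps the pairs together and sets numbers 1 and 4, the lymph node libraries, against 2 and 3. Of the 8 splits that part all 4 pairs, 1, the real one, gave 2 genes (highest other 0), and 8 splits are too few for a share under 0.05. Splits with several times the real count point to a structure of the samples. With corticosterone 1 of 35 splits gave its 1 gene (highest other 0), a share under 0.05 and the smallest that 35 splits can give. Shares were not adjusted over the comparisons, so chance is made less likely for this count of 1 gene and is not excluded. Averaged over conditions 3 of 100 splits gave at least the 7 genes (highest other 1124), a share under 0.05. Of 100 splits that part all 4 high-fat diet pairs, 1, the real one, did (highest other 2). This second set was chosen after the result, with pairs taken from the same data, so it is no separate test. Chance is made less likely for this count and is not excluded. For the high-fat diet the real split alone, 1 of 35, gave 5758 genes in controls (highest other 3277) and 4813 in FMRKO mice (2346). For corticosterone 1 of 35 gave 8453 in controls (462) and 8102 in FMRKO mice (27). Each share is the smallest that 35 splits can give and argues against chance as the source of these counts. For the differences between conditions edgeR found 0 genes (1939 and 1171 at an unadjusted p under 0.05, and 13 and 4 in DESeq2), which any split reaches, so the 100 of 100 splits in each say nothing about chance. The highest other splits gave 3881 and 2 genes.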
